A study of Mus musculus with 4 samples.

How the data were processed

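Gene expression was measured by RNA sequencing in 4 libraries of sorted mouse hair follicle stem cells, 2 labelled WT (replicates A and C) and 2 labelled Foxp3-DTR (replicates C and D). Per the labels' protocols, libraries were made with a stranded poly(A) mRNA kit. The deposited values are counts: whole numbers of reads per gene symbol, 1 column per library, not normalized. Per the submitters' processing notes, the tools included CASAVA 1.8.2, TopHat2 2.0.12, Bowtie2 2.1.0.0, SAMtools 0.1.19.0 and HTSeq 0.6.1, with genome build mm10. The gene annotation and the strand setting of the counter are not given in the sources used here. Without that setting, reads from a gene and from an overlapping or antisense neighbour cannot be told apart, and genes with near-identical copies are reported as uncertain.

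The deposited count table held 24084 gene rows and 5 special rows of the counter that name no gene. The special rows took 70.1% of the table's counts in WT A, 62.0% in WT C, 63.9% in Foxp3-DTR C and 67.8% in Foxp3-DTR D. Most of these were alignments that were not unique, which made up 51.8% to 61.3% of the counts in a library. They were left out of library sizes and tests. The table also held 27 gene names that looked like calendar dates, which were never named as genes. No mitochondrially encoded gene was found under its usual symbol, so that list had no members to test.

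Gene counts summed to 13911765 in WT A, 15923154 in WT C, 15493876 in Foxp3-DTR C and 14351776 in Foxp3-DTR D. A count of 0 allows up to 3 counts, which is 0.211, 0.185, 0.199 and 0.213 CPM (counts scaled to a common library size) in these libraries. Over a whole group the same floor of 3 counts was used for lower bounds on fold changes. With 1 to 3 counts in a group, a ratio with an exact 95% counting interval was used. Such floors and intervals cover counting error only.

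Foxp3-DTR was compared with WT in R 4.3.3 with edgeR 4.0.16, using TMM factors, the filterByExpr filter, robust glmQLFit and glmQLFTest. P-values were adjusted by the Benjamini-Hochberg method over the 12920 genes tested, with a threshold of 0.05. The model held the group and no covariate, as fixed before the data were examined. The common biological coefficient of variation was 0.31. CPM values are given as mean ± SD over n = 2 libraries. Standard errors of log2 fold changes were derived from the fold change and the quasi-likelihood F statistic. No sources used here state that the libraries came from separate animals, so p-values measure only the spread between these libraries, which may be technical.

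Before the data were examined, 29 gene lists were fixed: 18 pathways, 5 quality lists and 6 cell type lists. Lists with at least 5 tested genes were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over lists of the same kind. The alternatives were camera with an estimated correlation and fry, which asks whether a list's genes move on balance in 1 direction. With an estimated correlation, camera also takes its degrees of freedom from the 4 libraries, which leaves few, so a list can rarely pass. Members past the threshold were counted in the adjustment over all genes and in an adjustment over the list alone. The list of sex-linked genes was given as values per library, with no list test.

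The genes named in the text followed a rule fixed before the data were examined. It took the 8 largest rises and the 8 largest falls among genes past the threshold with an average log2 CPM of at least 2 and non-overlapping groups, leaving out predicted genes. It took up to 3 passing members with the smallest p from each pathway list and up to 2 from each quality or cell type list. Where a list had none, its member with the smallest p was taken and given as not passing. It also took the 3 smallest p-values in each direction, and in every case Foxp3, Hbegf, Jag1, Notch1, Cd34, Lgr5 and Sox9. Of the genes the rule took, 1 is not reported here. Genes outside the rule were chosen after their values were seen, except Xist, a member of the sex-linked list. Coordinates are from the GENCODE M21 gene annotation of GRCm38, the assembly that mm10 names, matched by symbol, and 95.7% of the tested symbols matched.

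The procedure was tested on simulated counts of the 12920 genes, drawn from the means and library sizes of the real libraries. The 200 changed genes were taken only from genes with an average log2 CPM above 2. It recovered 20% of 2-fold, 80% of 4-fold, 92% of 8-fold and 94% of 16-fold changes, with 8 false calls. In 100 random lists, 1 reached an unadjusted camera p under 0.05. The simulated genes were drawn independently of each other. This check therefore does not cover correlation within the real lists, estimated at 0.73 for S phase and DNA replication and 0.82 for mitosis. Of the 40 real mitosis genes, with a median log2 fold change of -2.25, 2 passed over all genes. The recovered shares therefore cannot be carried over to the real genes.

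The alternatives were DESeq2 size factors, upper-quartile factors, no filter, a stricter filter of at least 1 CPM in every library of a group, DESeq2 1.42.0, limma-voom, and each library left out in turn. A model with the level of interfollicular differentiation genes as a covariate, and a fit of autosomal genes only, were added after seeing the data.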

Results

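The series profiled hair follicle stem cells, the sorted epidermal cells that fuel hair regrowth, from back skin of mice aged 7 to 10 weeks, 4 days after depilation. Depilation, the removal of hair shafts, starts a new growth phase of the follicle. All mice received diphtheria toxin at 15 ng/g. In Foxp3-DTR mice the toxin's receptor is made in Foxp3-expressing regulatory T cells, so the toxin depletes them, and WT mice keep them. The comparison of 2 Foxp3-DTR with 2 WT libraries asks how the stem cells' expression differs when regulatory T cells are missing. Gene counts per library ranged from 13911765 to 15923154.

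Foxp3 itself had 0 counts in all 4 libraries, which allows at most 0.213 CPM in any library. In sorted stem cells this value does not check the depletion of T cells. The groups also differed in sex-linked genes. Xist, the RNA that silences an X chromosome in females and a member of the fixed sex-linked list, stood at 861 CPM in WT A and 2482 CPM in WT C. It stood at 1.86 CPM in Foxp3-DTR C and had 0 counts in Foxp3-DTR D. In edgeR's test over all genes 0 members of that list fell, so Xist did not pass. The Y-linked genes Eif2s3y, Ddx3y, Uty and Kdm5d had 0 counts in both WT libraries and were at least 982-fold, 1025-fold, 505-fold and 436-fold higher in Foxp3-DTR. Together they reached 319 CPM in Foxp3-DTR C and 260 CPM in Foxp3-DTR D. Group and sex of the animals therefore cannot be told apart in any comparison made here. The sample titles also carry the code DEP2 in both WT libraries and DEP3 in both Foxp3-DTR libraries. Whatever this code marks cannot be told apart from group either.

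The replicates of each group differed in keratinocyte differentiation genes, and the genes of this paragraph were chosen after their values were seen. Krt10, a keratin of suprabasal epidermis, stood at 4562 CPM in WT A and 249 CPM in WT C, and at 458 CPM in Foxp3-DTR C and 3796 CPM in Foxp3-DTR D. Krt1, its partner keratin, ran from 167 CPM in WT C to 2097 CPM in WT A. The basal keratins Krt5 and Krt14 ranged from 11783 to 15425 CPM and from 3386 to 4079 CPM. Scd1, a lipid synthesis enzyme abundant in sebaceous glands, stood at 1336 CPM in WT A and between 119 and 237 CPM in the other 3 libraries.

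**Figure D1:**
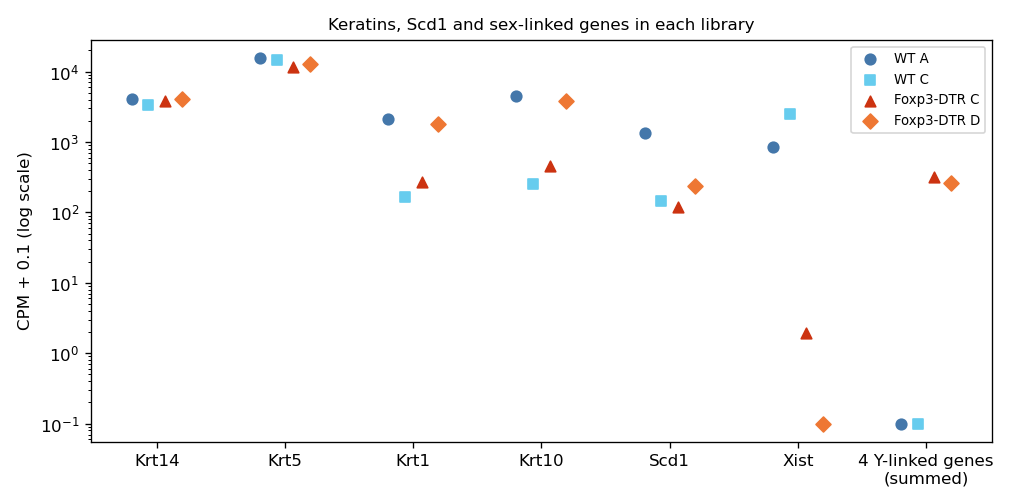
Expression of Krt14, Krt5, Krt1, Krt10, Scd1, Xist and the sum of 4 Y-linked genes in each of the 4 libraries, in CPM plus 0.1 on a log axis, 1 point per library. Krt1 and Krt10 are high in WT A and Foxp3-DTR D, Xist is high in both WT libraries, and the Y-linked genes are present only in both Foxp3-DTR libraries. The keratins and Scd1 were chosen after their values were seen.

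Of 12920 genes tested, 106 were higher and 55 lower in Foxp3-DTR in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The excess of rises depended on the method: DESeq2 gave 489 higher and 514 lower, no filter 277 and 252, limma-voom 70 and 23, and an unadjusted p under 0.05 in edgeR's test 873 and 1019. The metallothionein Mt2, a metal-binding stress protein (mm10 chromosome 8, 94172664 to 94173568), rose from 68.8 ± 6.06 to 1132 ± 31.4 CPM (SD, n = 2 per group). Its log2 fold change was 4.04 ± 0.21 (SE), with an edgeR adjusted p of 0.00307. Serpina3m, a member of a family of closely related serine protease inhibitors whose reads are uncertain, had 0 counts in WT and was at least 231-fold higher. The secreted protein gene Pi15 (chromosome 1, 17601901 to 17630939) fell by 3.39 on the log2 scale, from 466 ± 12.8 to 44.3 ± 3.77 CPM (edgeR adjusted p = 0.00307). Other large falls were in Gdf10, a secreted TGF-beta family member (log2 fold change -3.29 ± 0.33), Pcsk6, a proprotein convertase (-2.50 ± 0.20), and Crispld1 (-2.10 ± 0.19). Cyp27b1, which activates vitamin D, Col14a1 and Mns1 fell too, with log2 fold changes of -2.67, -2.73 and -2.999. Of the 161 genes, 151 were autosomal, 4 on Y and 3 on X, and 3 had no chromosome by symbol. Without Foxp3-DTR C the counts were 66 higher and 14 lower, without WT C 190 and 160, and without Foxp3-DTR D 203 and 220. Groups did not overlap for 45.7% of tested genes, against 33.3% by chance.

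Most genes of the NF-kappaB and TNF response had positive fold changes, and a minority passed over all genes. Of 24 tested members 5 rose over all genes and 17 adjusted over the list alone, and 22 had a positive fold change, with a median log2 fold change of 1.21. Icam1, an adhesion molecule for leukocytes (chromosome 9, 21015985 to 21028817), rose from 22.4 ± 3.90 to 280 ± 78.0 CPM, a log2 fold change of 3.64 ± 0.28 (edgeR adjusted p = 0.00503). The feedback inhibitor Nfkbia rose by 1.83 ± 0.20 and the transcription factor Relb by 1.95 ± 0.28. Bcl3, a nuclear NF-kappaB cofactor, rose by 7.30 ± 0.98 from 8 counts in WT, and the chemokine Ccl7 was at least 121-fold higher than the 0 counts in WT. The list passed camera (adjusted p = 1.44e-20), with an adjusted p of 0.337 with an estimated correlation. DESeq2 called 12 of 27 members higher over all genes, and limma-voom 2 of 24. Without Foxp3-DTR C, 3 members rose over all genes and 10 adjusted over the list alone.

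Interferon response and antigen presentation genes had higher levels in Foxp3-DTR, with most members passing only within their list in edgeR's test. Of 39 interferon genes 1 rose over all genes and, adjusted over the list alone, 30 rose and 1 fell, with a median log2 fold change of 2.68. The member over all genes was Irf9, part of the interferon transcription factor complex, with a log2 fold change of 2.26 ± 0.25 (edgeR adjusted p = 0.0184). The member that fell was Ifit2, named after its value was seen. Of 24 antigen presentation genes 2 rose over all genes and 15 adjusted over the list alone, with a median of 1.48. These 2 were the immunoproteasome subunits Psmb10, from 8.06 ± 1.74 to 76.2 ± 37.4 CPM, and Psmb8, from 17.1 ± 1.34 to 135 ± 75.2 CPM. The camera adjusted p was 1.95e-24 for the interferon list and 1.03e-15 for antigen presentation. Both had an adjusted p of 0.337 with an estimated correlation. DESeq2 called 27 of 51 interferon genes higher and 1 lower over all genes, and 15 of 24 antigen presentation genes higher. Limma-voom called 1 of 39 and 0 of 24 higher. The 2 Foxp3-DTR libraries differed: Cxcl10, chosen after its values were seen, stood at 82.9 CPM in replicate C and 6.80 CPM in replicate D, and at 0.845 and 0.369 CPM in WT A and WT C. Without Foxp3-DTR D, 26 interferon and 14 antigen presentation genes rose over all genes, and without Foxp3-DTR C 4 and 2, with medians of 1.63 and 0.925. Over all genes, 0 antigen presentation genes rose without WT A, without WT C or with limma-voom. Adjusted over the list alone, 6 interferon and 11 antigen presentation genes rose without WT A, and 2 and 9 without WT C.

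Injury, hypoxia and immediate early genes were tested as 3 further lists. Of 19 keratinocyte injury and IL-17 genes 2 rose over all genes and 3 adjusted over the list alone. Lcn2, which binds bacterial siderophores, rose by 7.14 ± 0.83 from 5 counts in WT, and the neutrophil chemokine Cxcl1 had a ratio of 179 (exact 95% counting interval 49.2 to 1484) on 2 counts in WT. Of 28 hypoxia and glycolysis genes 1 rose over all genes, the oxygen sensor Egln3 (2.33 ± 0.19), and 3 adjusted over the list alone. Of 33 dissociation and immediate early genes 7 rose over all genes, and 8 rose and 1 fell adjusted over the list alone. Without Foxp3-DTR C, 3 rose over all genes. Those that rose included the cytokine signalling inhibitor Socs3 (2.69 ± 0.19, edgeR adjusted p = 0.0033) and Ier3 (2.20 ± 0.21). Fos and Hspa1a, chosen after their values were seen, had log2 fold changes of 0.44 ± 0.53 and 0.30 ± 0.20 and did not pass. The camera adjusted p was 0.00425, 0.00155 and 2.71e-08 for these lists, and with an estimated correlation the adjusted p was 0.337, 0.337 and 0.0727. Without Foxp3-DTR D the injury list had a camera adjusted p of 0.165.

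Cell cycle genes were lower in Foxp3-DTR. All 40 tested genes of S phase and DNA replication and all 40 of mitosis had negative fold changes, with median log2 fold changes of -1.53 and -2.25. Over all genes 5 and 2 fell, and adjusted over the list alone 37 and 39. The replication genes over all genes were Hells, Dtl and Clspn, with Pole and Mcm6, which are named after their values were seen. Hells, a chromatin remodeller (chromosome 19, 38930915 to 38971051), fell by 1.94 from 71.7 ± 7.67 to 18.6 ± 0.194 CPM (edgeR adjusted p = 0.0157). Dtl, which targets licensing factors for degradation, fell by 2.21, and Clspn, a checkpoint adaptor, fell by 2.63. In mitosis, the spindle motor Kif11 fell by 2.30 from 91.9 ± 19.8 to 18.7 ± 6.20 CPM, and the kinase Aurka fell by 2.21. The camera adjusted p was 8.68e-40 for both lists, and the adjusted p was 0.337 for both with an estimated correlation. The epidermal covariate, added after seeing the data, was computed from these same counts. It takes up differences between the replicates of each group, which by itself can raise the number of calls. With it, 36 replication and 37 mitosis genes fell over all genes, and with DESeq2 and no covariate, 35 and 36. Without Foxp3-DTR D, 16 and 33 fell, without Foxp3-DTR C, 1 and 2 fell, with limma-voom, 1 and 1 fell, and without WT A, 3 and 1 fell, with 17 mitosis genes adjusted over the list alone.

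Of 19 hair germ and hedgehog genes 1 fell over all genes, and 1 rose and 7 fell adjusted over the list alone. Without WT C, 1 rose and 0 fell over all genes, and without Foxp3-DTR C, 3 fell adjusted over the list alone. The gene that fell over all genes was Sostdc1, a secreted Wnt and BMP modulator (chromosome 12, 36314139 to 36318452), which fell by 2.50 from 604 ± 74.9 to 107 ± 51.3 CPM (edgeR adjusted p = 0.0441). The list's median was -0.46, with a camera adjusted p of 0.000345 and an adjusted p of 0.337 with an estimated correlation. Without WT C its camera adjusted p was 0.056.

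Bulge stem cell identity genes had fold changes of both signs. Of 27 tested, Angptl4, a lipase inhibitor, rose by 3.60 ± 0.41, and the basement membrane protein Npnt fell 2.82-fold from 810 ± 44.4 to 287 ± 13.7 CPM (edgeR adjusted p = 0.0188 and 0.0281). Adjusted over the list alone 5 rose and 7 fell, against 2 and 4 without WT A, 1 and 1 without Foxp3-DTR C and 1 and 2 without Foxp3-DTR D. The median was -0.14 and the mean 0.10, with a camera adjusted p of 0.791. Camera looks for a shift in 1 direction and cannot show changes of both signs. Fry's mixed form, which takes either direction, gave an unadjusted p of 0.0013. It was low for other lists too, such as hypoxia and glycolysis (0.00072). The bulge markers Cd34, Sox9 and Lgr5 had log2 fold changes of 0.63 ± 0.22, -0.15 ± 0.19 and -0.14 ± 0.25, with edgeR adjusted p of 0.239, 0.804 and 0.876. Cd34 stood at 1076 ± 198 CPM in WT and 1667 ± 59.1 CPM in Foxp3-DTR.

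In Notch signalling 0 of 28 genes passed over all genes in edgeR's test (camera adjusted p = 0.286), and adjusted over the list alone 1 rose and 2 fell. At an unadjusted p under 0.05 there were 5, limma-voom called 0, DESeq2 called 2 higher and 2 lower of 33, and the epidermal covariate gave 4 higher and 2 lower. The Notch ligand Jag1 stood at 260 ± 80.4 CPM in WT and 392 ± 61.5 CPM in Foxp3-DTR, a log2 fold change of 0.59 ± 0.26 with an edgeR adjusted p of 0.380. Notch1 had 0.40 ± 0.22 (edgeR adjusted p = 0.489). Hes1, a target of the pathway, had -2.09 ± 0.35 and an edgeR adjusted p of 0.0523, just outside the threshold. Hbegf, a growth factor, had 0.36 ± 0.55 (edgeR adjusted p = 0.846). The Wnt ligand Wnt5b fell by 1.75 and the BMP antagonist Grem1 by 1.40, with 1 member each past the threshold over all genes. Their lists had camera adjusted p of 0.718 and 0.988.

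**Figure D2:**
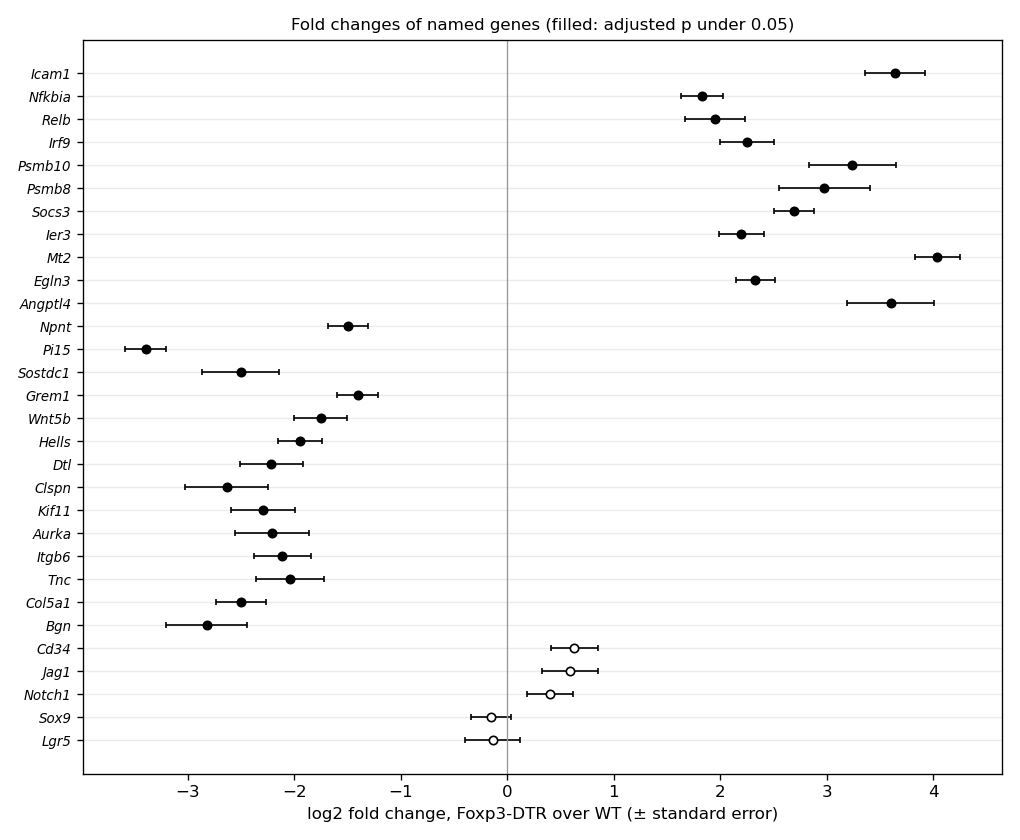
Log2 fold changes of 30 named genes, Foxp3-DTR over WT, with standard errors derived from the quasi-likelihood F statistic. Filled points passed an adjusted p of 0.05 and open points did not. NF-kappaB, interferon and antigen presentation genes lie to the right, replication and mitosis genes to the left, and Cd34, Jag1, Notch1, Sox9 and Lgr5, all open, between -0.15 and 0.63.

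The other pathway lists did not pass camera. The adjusted p was 0.127 for adhesion and basement membrane, where the integrin Itgb6 and the matrix protein Tnc fell, with log2 fold changes of -2.11 and -2.04. It was 0.718 for interfollicular differentiation, where Calml3 fell by 1.57, and 0.718 for inner root sheath and hair shaft, where Krt27 had 3.25 ± 0.71 and an edgeR adjusted p of 0.0846. It was 0.867 for outer root sheath, with Barx2 at -1.13 ± 0.20 (edgeR adjusted p = 0.0551), 0.718 for cholesterol biosynthesis, with Ebp at 1.13 ± 0.28 (0.118), and 0.589 for p53 and apoptosis. The outer root sheath list had a negative median and a positive mean, interfollicular differentiation a negative median and positive mean, and BMP a positive median and negative mean. Single libraries decided some of these lists, in camera adjusted p. Interfollicular genes were higher without WT A (0.0126) or Foxp3-DTR C (0.00142) and lower without WT C (0.0177) or Foxp3-DTR D (0.000308). Outer root sheath genes were higher without Foxp3-DTR C (0.0119), and adhesion genes lower without WT A (0.00433). Cholesterol genes were higher without WT A (0.000617) and lower without WT C (1.35e-06).

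Lists of other cell types and of RNA quality were tested in the same way. Of 15 tested fibroblast and dermal papilla genes 2 fell over all genes, the collagen Col5a1 by 2.50 and the proteoglycan Bgn by 2.82, and 5 fell adjusted over the list alone. Their camera adjusted p was 0.000264 and the adjusted p with an estimated correlation 0.363. Fold changes were positive for 5 of the 15 and negative for 10. The untested members Col3a1, Lum, Dpt and Mfap5, named after their values were seen, had at most 1 count in any library. The list therefore cannot tell whether the share of fibroblasts differed. Camera adjusted p was 0.499 for T cells, 0.344 for macrophages, Langerhans cells and granulocytes, 0.0627 for melanocytes and nerve, and 0.0649 for sebaceous gland and infundibulum. Their members with the smallest p did not pass: Tnfrsf4 had a log2 fold change of 1.59 ± 0.44, Pmel 1.497 ± 0.52 and Prdm1 -0.91 ± 0.24. Fcer1g, not passing either (edgeR adjusted p = 0.218), had a ratio of WT over Foxp3-DTR of 28.7 (exact 95% counting interval 4.78 to 1173) on 30 counts in WT and 1 count in Foxp3-DTR. Endothelium had 4 tested genes and no list test, and its Acta2 had -3.22 ± 1.18. Ribosomal protein genes had a median of 0.23 (camera adjusted p = 0.0103, and 0.539 with an estimated correlation). In that list Rps18 rose by 2.05 and Rpl11 fell by 2.57, both with near-identical copies in the genome and so uncertain. The 6 tested histone genes had a median of -1.26 (camera adjusted p = 0.0103, and an adjusted p of 0.478 with an estimated correlation), and Hist1h2bc had -1.37 ± 0.41, not passing. The camera adjusted p of ribosomal genes was 0.829 without WT C and 0.132 without Foxp3-DTR D, that of histones 0.11 without Foxp3-DTR C, and that of sebaceous genes 6.49e-08 without WT C.

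**Figure D3:**
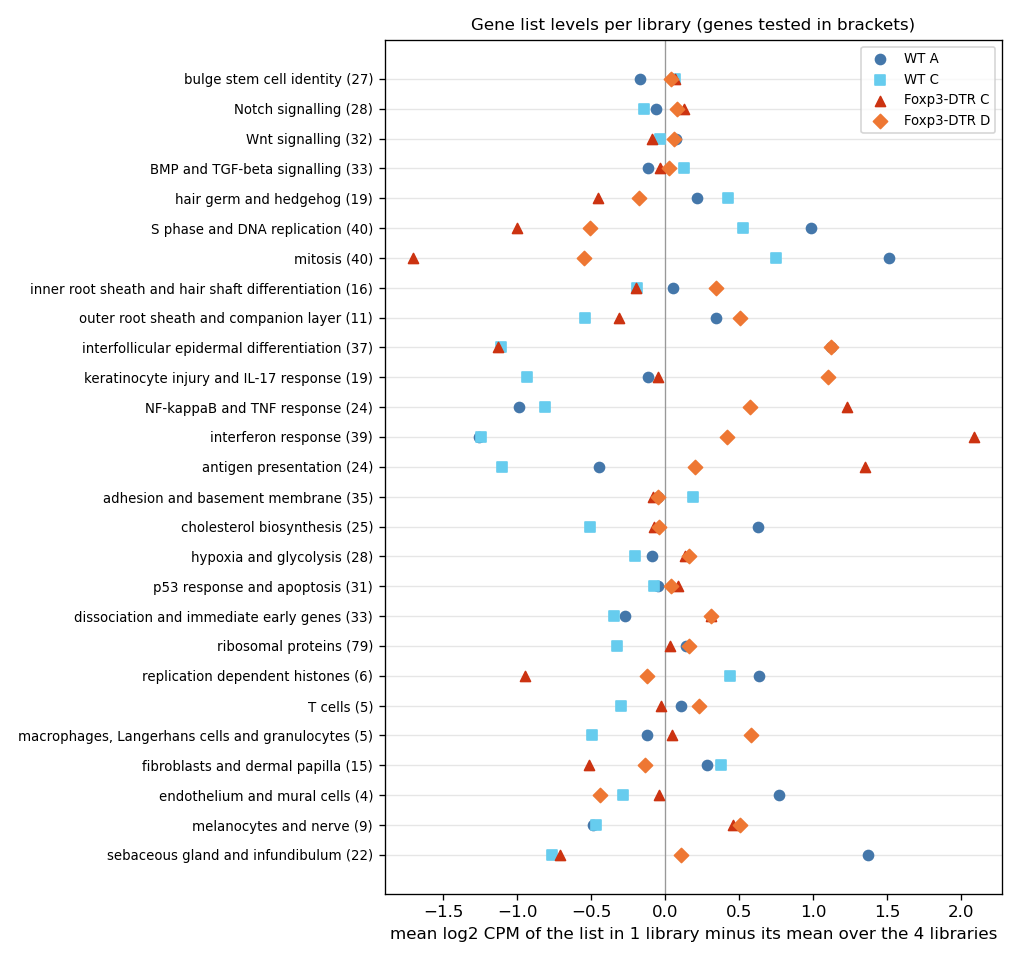
Mean log2 CPM of each gene list in each library, minus its mean over the 4 libraries, 1 point per library, with the number of genes tested in brackets. Mitosis runs from 1.51 in WT A to -1.71 in Foxp3-DTR C, and interferon genes from -1.26 in WT A to 2.09 in Foxp3-DTR C, while interfollicular genes part the replicates of each group.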

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

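The epidermal covariate and the fit of autosomal genes were chosen after seeing the data, and the other alternatives before the data were examined. The covariate was computed from these same counts, at 1.12 in WT A, -1.11 in WT C, -1.13 in Foxp3-DTR C and 1.12 in Foxp3-DTR D. It parts the replicates of each group, so its larger counts of genes may be partly built in. All 161 genes kept their sign in every alternative that tested them. Higher and lower genes numbered 277 and 252 with no filter, 489 and 514 with DESeq2, 70 and 23 with limma-voom and 567 and 632 with the epidermal covariate, and the stricter filter gave 152 and 109. Of the 106 and 55 genes, limma-voom shared 67 and 23. With 1 library left out, the counts ranged from 66 to 203 higher and from 14 to 220 lower, where the lone library is assumed to vary like the other group. The other splits of the 4 libraries gave 0 genes each in edgeR's test. At an unadjusted p under 0.05 they gave 32 and 634, against 1892 for the real split. Each of them sets 1 WT and 1 Foxp3-DTR library on each side, so the group difference counts as spread and lowers the calls by construction. The split with 634 sets WT A and Foxp3-DTR D, both high in interfollicular genes, against the others. These splits are therefore no test of chance, and 3 splits are too few for a share under 0.05. No paired analysis was possible because the groups share only 1 replicate letter.

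With an estimated correlation, the adjusted p was 0.337 for hair germ, S phase, mitosis, injury, NF-kappaB, interferon, antigen presentation and hypoxia, 0.0727 for dissociation, 0.539 for ribosomal proteins, 0.478 for histones and 0.363 for fibroblasts, so no list passed. The shared 0.337 is a tie made by the adjustment, over unadjusted camera p from 0.0609 for hypoxia to 0.15 for injury. The estimated correlations of hypoxia (-0.00822) and dissociation (0.00304) were below the preset 0.01. A higher correlation therefore does not account for the larger p of these 2 lists. The few degrees of freedom left by 4 libraries also raise p in this form of camera, whatever the correlation. Not passing it is therefore no evidence that a list did not change. With fry the adjusted p was 0.174 for hair germ, S phase, NF-kappaB and hypoxia, 0.215 for mitosis, 0.288 for injury, 0.267 for interferon and antigen presentation, 0.38 for ribosomal proteins, 0.156 for histones and 0.104 for fibroblasts, while dissociation kept its call (0.0328). The injury list had 0.0506 with limma-voom and histones 0.061 with no filter. Melanocytes passed with the stricter filter (0.0286), limma-voom (0.0292) and fry (0.0456), and sebaceous gland with the stricter filter (0.0432). BMP turned downward with no filter (0.999), the stricter filter (0.974), fry (0.996) and the epidermal covariate (0.994), and T cells with no filter (0.635). The cause was not tested.

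With each library left out, adjusted p ranged from 0.267 to 0.962 for bulge identity, 0.35 to 0.962 for BMP, 2.48e-05 to 0.056 for hair germ, 0.232 to 0.923 for inner root sheath, 0.0119 to 0.923 for outer root sheath and 9.72e-09 to 0.165 for injury. Interfollicular differentiation ranged from 0.000308 to 0.0177, upward without WT A or Foxp3-DTR C and downward without WT C or Foxp3-DTR D. Adhesion ranged from 0.00433 to 0.828, cholesterol from 1.35e-06 to 0.83, ribosomal proteins from 8.23e-08 to 0.829, histones from 0.00529 to 0.11, T cells from 0.0787 to 0.811, macrophages from 0.321 to 0.838 (not tested without WT A) and sebaceous gland from 6.49e-08 to 0.304. Cholesterol and sebaceous gland turned upward without WT A, and adhesion without WT C. Bulge identity turned upward without WT C or Foxp3-DTR D. BMP turned downward without WT A or Foxp3-DTR D, inner root sheath without Foxp3-DTR D, and outer root sheath without WT C or Foxp3-DTR D. T cells turned downward without WT C, Foxp3-DTR C or Foxp3-DTR D, and macrophages without WT C. Lgr5 had a log2 fold change from -0.40 without WT A to 0.21 without WT C. Fewer libraries are the alternative's own construction, and the cause was otherwise not tested. Depth limits the low genes: Ccl7, Serpina3m and the Y-linked genes have lower bounds only.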

Other observations

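Some genes outside the lists, chosen after their values were seen, also passed the threshold. Mt1 rose by 3.13 on the log2 scale, the acute-phase transcription factor Cebpd by 3.80, the NF-kappaB inducing kinase Map3k14 by 3.69 and the DNA sensor adaptor Tmem173 by 5.12. Stat3 rose by 1.48, Osmr, a cytokine receptor, by 2.11, and the skin chemokine Ccl27a by 2.96. All had edgeR adjusted p from 0.0033 to 0.0427. Among genes that fell were Brca1 at -1.92, Pold1 at -1.54 and Rad54l at -2.45, which act in DNA repair or synthesis.

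All tests in the paragraphs that follow were chosen after the results were seen. The first pattern is the higher levels of NF-kappaB, interferon and antigen presentation genes, of which 5 of 24, 1 of 39 and 2 of 24 rose over all genes, with an adjusted p of 0.337 for each list with an estimated correlation. RNA from leukocytes in the Foxp3-DTR libraries was tested, in place of an earlier test on hand-picked genes, on all 50 members of the T cell and myeloid lists found in the table: 5 (10%) were higher in both Foxp3-DTR than in both WT libraries, and 24 had no count in either Foxp3-DTR library. The 5 were Tnfrsf4, Cd8b1, Cd68, Kit and Cxcr2, the last with 2 and 0 counts in WT A and WT C and 16 and 22 in Foxp3-DTR C and D. Some of the 24, such as Cd4, had no count in WT either and cannot decide. The pan-leukocyte gene Ptprc, picked after its values were seen, had 24 and 5 counts in WT A and WT C and 2 and 0 in Foxp3-DTR C and D. B2m went from 676 to 1629 CPM. With the 10% share, these values argue against leukocytes as the main source. Summed over all 50 members, CPM was higher in Foxp3-DTR (95.2 and 77.4) than in WT (55.8 and 47.9), but not without Tnfrsf4 (24.6 and 36.6 against 43.9 and 22.9). Stress from dissociation or sorting stays open, its list having a camera adjusted p of 0.0727 with an estimated correlation but 0.0328 with fry. The list's median log2 fold change was 0.442 (bootstrap 95% interval 0.280 to 0.813). The bootstrap drew the list's 33 genes as if independent, so this interval leaves out the spread between libraries. The absence of regulatory T cells, which the design names, stays open too. So does sex of the animals, since Y-linked genes reached at least 260 CPM in Foxp3-DTR and 0 in WT.

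The second pattern is the lower levels of replication and mitosis genes, of which 5 of 40 and 2 of 40 fell over all genes, with an adjusted p of 0.337 for each list with an estimated correlation. Different shares of differentiated epidermal cells, which would dilute the RNA of dividing cells, were tested within the groups: the median log2 level of the 80 genes was not lower in the library with the higher interfollicular level but higher, by 0.642 in WT and 0.745 in Foxp3-DTR, which argues against such shares as the whole cause. This test replaced a covariate fit and then matched pairs of libraries after their values were seen. That level averaged 0.00608 in WT and -0.00609 in Foxp3-DTR, and between libraries nearly equal in it (apart by 0.0234 and 0.0009) all 80 genes were lower in Foxp3-DTR, with medians of -2.07 and -1.91. Sex of the animals cannot be told apart from the group, with Xist at most 1.86 CPM in Foxp3-DTR and at least 861 CPM in WT, and the absence of regulatory T cells is untested apart from it.

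The third pattern is the difference in suprabasal genes between replicates of each group. Of 37 interfollicular genes, 33 were higher in WT A than in WT C and also higher in Foxp3-DTR D than in Foxp3-DTR C. Of 22 sebaceous and infundibular genes, 14 were highest in WT A. Sequencing depth is argued against, since Krt10 differed by 4.196 and 3.05 on the log2 scale within the groups while never under 249 CPM. Differentiated epidermal cells sorted along with the stem cells and differentiation of the stem cells themselves predict the same counts, were not tested and cannot be told apart here.

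A hypothesis was that alleles carried along with the modified Foxp3 locus could change genes nearby. Within 10 Mb of Foxp3, 1 of 49 tested genes passed the threshold, no more than elsewhere beyond chance (one-sided Fisher's exact p = 0.46), which leaves the hypothesis open. That gene was Porcn, an enzyme that modifies Wnt proteins, which starts 0.62 Mb from Foxp3 and rose by 2.71 on the log2 scale. Its neighbour Ebp, which ends at 8193512 against Porcn's start at 8193848, had 1.13 ± 0.28 and did not pass. The strand setting of the counter is not given, so reads from such close neighbours may not be kept apart.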
